A study of Mus musculus with 3 samples.

How the data were processed

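RNA from 3 samples of E. coli-infected mouse bone marrow-derived dendritic cells was lysed in a phenol-based reagent, labelled with biotin and hybridised to 1 Affymetrix mouse whole-transcript gene array per sample, per the labels. Each array is 1 colour. The submitters' processing notes name Affymetrix Expression Console, and its version, the summarisation method and the normalization are not given in the sources used here. The deposited values are on a log2 scale, judged from their range of 1.81 to 13.12, which a 16-bit scanner could not give as a natural or base-10 logarithm. The 3 arrays had near-equal quartiles (lower quartiles of 3.33 each, upper quartiles of 6.41, 6.44 and 6.45), so the authors' values were taken as already normalized and were used as deposited. Scanner files were not used here, so background and saturation of single probes could not be assessed.

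The table holds 35556 probe sets. The platform annotation, which can be out of date, names a gene for 23410 of them, with 1 symbol for 21789 and several for 1621. The other 12146 are unnamed here and were not used. Symbols were updated through gene identifiers for 23312 probe sets and kept as given for 98. Probe sets with several symbols were left out, and a gene with over 1 probe set (999 genes) was represented by the one with the highest mean signal, which left 19938 genes. The probe sets of a gene can disagree: with their mean, Cd80 was at 10.59, Top2a at 4.50 and Hk1 at 8.31, in place of 10.78, 6.15 and 10.48. Genome coordinates are not given, because the files name no genome build. Closely related genes, such as the mast cell proteases, the Cxcl1 to Cxcl3 chemokines, the Ifit genes, the class II chains and olfactory receptors, may share probe sequence, and their separate signals are uncertain.

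Before the data were examined, 30 gene lists were fixed, 13 of cell type markers and 17 of pathways, with 403 entries. Of these, 371 were analysed. For 26 no probe set is named in the table used here, and 6 had only probe sets with several symbols; these are not analysed here. A gene in 2 lists counts in both. The genes named in the text follow a rule fixed at the same time: the first 4 measured members of each list, up to 4 members whose detection differs from most of the list, members past the variance test, the 4 members with the largest departure in a list that stands apart, and the 15 genes with the smallest p in the variance test. Not every gene that the rule names is printed. The genes of 5 further lists in the closing section, and Timp1, Kit, Gata2, Hdc, Prss34, Dcn and Thy1, were chosen after their values were seen.

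A gene was called detected where its mean log2 signal over the 3 arrays was above the 95th percentile of 1233 olfactory, vomeronasal and taste receptor genes, taken by name as background. By construction 62 receptor genes are above it. Each list's detected and undetected members were compared with all other non-receptor genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 30 lists. Genes are not independent replicates, and the other genes include predicted genes and small RNAs. Excess variance between arrays was tested with limma 3.58.1 in R 4.3.3. An intercept was fitted to the 12351 detected genes, and eBayes with a trend on mean signal gave a prior variance with 10.97 degrees of freedom. The ratio of a gene's variance to its prior variance was referred to the upper tail of the F distribution, adjusted by Benjamini-Hochberg at 0.05. List departures were the median over detected members of the log2 signal minus the gene's 3-array mean. They were placed among 10000 random lists of detected genes matched on mean signal in 20 bins, for the 22 lists with at least 5 detected members. The rank share is two-sided, and a list stands apart where it is under 0.002. Figures were drawn with matplotlib 3.10.9.

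The tests were checked on simulated data for the 12351 detected genes, with the real means and with variances drawn from the fitted prior. Of 100 genes given 8 times their SD, 53 were called, and of 100 given 4 times their SD, 15 were called. Smaller excesses of variance can thus be missed. No gene was called among the 12151 unchanged ones. Their variances followed the prior that the test assumes, so this does not show how often real genes are falsely called. A shift of 0.2 log2 units added to the chemokine list in 1 array gave a departure of 0.13 that stood apart, and none of the 66 list and array pairs stood apart without a shift. The simulated genes were drawn independently of each other, whereas the genes of a real list are co-regulated. The result without a shift therefore does not show how often a co-regulated list stands apart through ordinary variation between arrays. A list made up of 15 detected genes passed Fisher's exact test, and a random list with 9 of 15 detected did not. The first result was fixed by the choice of genes, so it does not test the method. Neither result shows how often a list of co-regulated genes passes falsely. Alternatives covered the background percentile, detection in every array, the mean of all probe sets, quantile normalization, median centring, probe sets with several symbols, the detection filter, the prior variance, the matching and summary of lists, and leaving out each replicate.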

Results

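Gene expression was measured in mouse bone marrow-derived dendritic cells (BMDCs), cells grown from bone marrow with the growth factor GM-CSF, that had been exposed to live E. coli. The cells were examined on day 4 after infection, per the study design. The 3 arrays form 1 group of 3 replicates, and uninfected cells were not analysed here, so no value below is a response to infection. The questions that this design allows are which gene groups gave signal above background in the infected cells and how closely the replicates matched. Each gene is given as its log2 signal, as mean ± SD over n = 3 arrays. The number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures or animals, so p-values on the spread between arrays may reflect technical spread alone.

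The 3 arrays gave closely similar values. Across the 19938 genes, which are not independent replicates, Pearson's r was 0.997 for each pair of arrays. The SD of the log2 difference was 0.160 between replicates 1 and 2, 0.166 between replicates 1 and 3, and 0.158 between replicates 2 and 3. No array was a copy of another, as the SDs of these differences show. The median SD of a detected gene over the 3 arrays was 0.0884 log2 units. Only 2 to 3 genes per pair differed by more than 1 log2 unit. The median signal was 4.38, 4.37 and 4.37 in replicates 1, 2 and 3.

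Background was set by 1233 olfactory, vomeronasal and taste receptor genes, whose median signal was 2.96. Their 95th percentile, 3.95, was the level above which a gene was called detected. By this rule 12289 of the other 18705 genes (65.7%) were detected. The level of a gene is compared with this background only, because probe sets of different genes bind with different strength.

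The measured genes of antigen presentation were detected together. All 12 measured MHC class II genes were above background, among them the class II chains H2-Aa (10.93 ± 0.062), H2-Ab1 (11.06 ± 0.0076) and H2-Eb1 (11.25 ± 0.065) and the invariant chain Cd74 (11.13 ± 0.042). All 11 measured MHC class I genes were also above background. The class I heavy chain genes of the list, H2-K1 and H2-D1, were not among those analysed. They included B2m, the light chain of class I molecules (11.68 ± 0.018), the peptide transporter subunits Tap1 (8.67 ± 0.077) and Tap2 (7.73 ± 0.041), and Tapbp (8.25 ± 0.11), which links the transporter to class I molecules. The class II list held more detected members than the other genes (two-sided Fisher's exact test, adjusted p = 0.0375 over the 30 lists). The class I list did not pass that test (adjusted p = 0.0615). Every measured member of both lists was detected, so this contrast reflects list length, 12 against 11 genes, and not a difference in detection. Where detection was required in every array, the class II list no longer passed (adjusted p = 0.118, with a range of 0.0105 to 0.118 over the alternatives) and the class I list did (adjusted p = 0.0357, range 0.00198 to 0.153).

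Dendritic cell maturation genes were detected in 17 of 18 cases. The costimulatory molecules Cd80 (10.78 ± 0.013), Cd86 (10.90 ± 0.020) and Cd40 (10.17 ± 0.035) and Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes (11.04 ± 0.043), lay more than 6 log2 units above background. Lamp3 was not detected (2.79 ± 0.13). The list passed the test against the other genes (Fisher's exact test, adjusted p = 0.0375). Of the 16 inhibitory and regulatory genes measured, 14 were detected. They included Cd274, which encodes the checkpoint ligand PD-L1 (10.62 ± 0.051), Pdcd1lg2, which encodes PD-L2 (8.56 ± 0.091), and the tryptophan-degrading enzyme Ido1 (8.77 ± 0.10). The anti-inflammatory cytokine Il10 (3.55 ± 0.10) and the arginase Arg1 (3.92 ± 0.095) were not detected. This list did not pass the test (Fisher's exact test, adjusted p = 0.107).

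**Figure D1:**
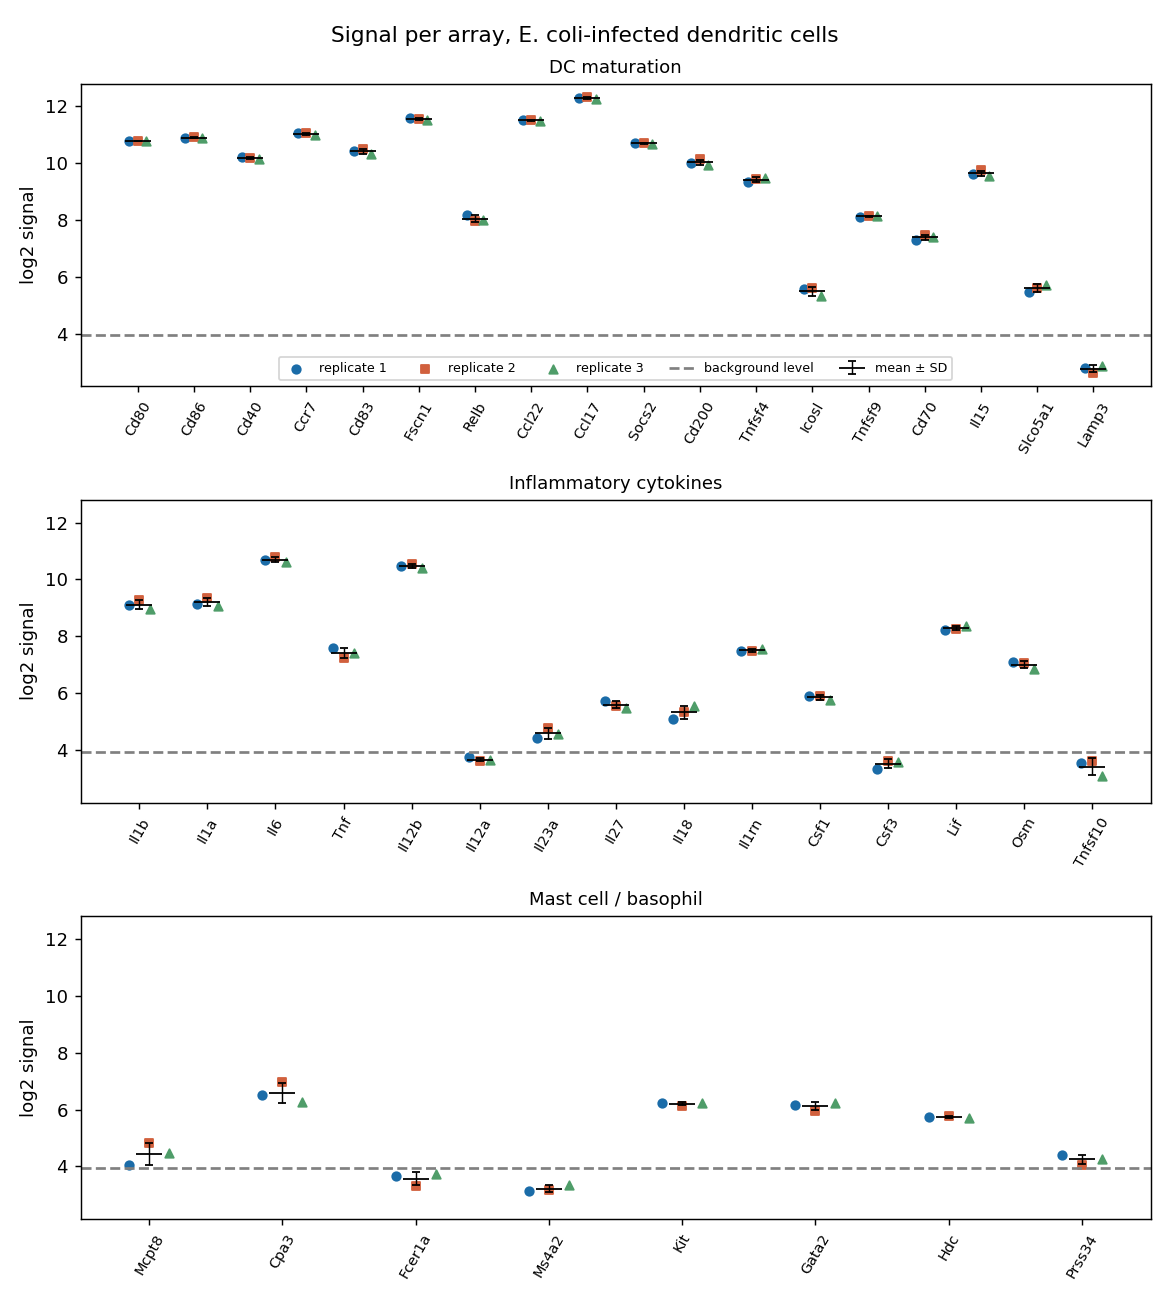
Log2 signal (vertical axis) of each gene (horizontal axis) of 3 lists in the 3 arrays, with the mean ± SD as a black bar and the background level of 3.95 as a dashed line. All but 1 of the 18 maturation genes lie above the line, 3 of the 15 cytokine genes lie below it, and 6 of the 8 mast cell and basophil genes lie above it.

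Inflammatory mediators were detected for the most part. Of 15 cytokine genes, 12 were above background, including Il1b (9.12 ± 0.17), Il1a (9.20 ± 0.14), Il6 (10.69 ± 0.089) and Tnf (7.42 ± 0.19). Il12a, which encodes the p35 subunit of interleukin-12 (3.68 ± 0.067), the granulocyte growth factor Csf3 (3.53 ± 0.16) and the death ligand Tnfsf10 (3.43 ± 0.30) were not. Il12b of the same list was detected (10.47 ± 0.074). All 15 chemokine and chemokine receptor genes were detected. The neutrophil attractants Cxcl1 (8.58 ± 0.071), Cxcl2 (9.90 ± 0.10) and Cxcl3 (8.90 ± 0.18) were well above background, and Cxcl5 was near it (4.16 ± 0.18). The chemokine list passed the test against the other genes (Fisher's exact test, adjusted p = 0.0135), and the cytokine list did not (adjusted p = 0.378). Interferon-stimulated genes were detected in 18 of 20 cases, with Ifit1 at 7.28 ± 0.085, Ifit2 at 5.73 ± 0.19, Ifit3 at 7.54 ± 0.093 and the antiviral GTPase gene Mx1 at 8.84 ± 0.031. Interferon beta itself (Ifnb1, 3.57 ± 0.10) and Cmpk2 (3.76 ± 0.11) were not detected, and the list did not pass (Fisher's exact test, adjusted p = 0.0766).

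Nearly all measured genes of the lists for sensing and killing bacteria were detected. All 21 genes of Toll-like receptor and NF-κB signalling were above background, among them the lipopolysaccharide receptor Tlr4 (6.29 ± 0.18), its co-receptors Cd14 (8.74 ± 0.22) and Ly96 (7.83 ± 0.083), and the adaptor Myd88 (7.09 ± 0.054). This list had the lowest adjusted p of the 30 (Fisher's exact test, adjusted p = 0.00759). It was also the longest, and among lists detected in full the p-value depends on length alone. Of 13 inflammasome genes, 12 were detected, with Nlrp3 at 6.65 ± 0.10, Casp1 at 8.14 ± 0.11, Casp4 at 9.01 ± 0.046 and Pycard at 9.11 ± 0.097. Nlrp1b was not (3.21 ± 0.12), and the list did not pass (Fisher's exact test, adjusted p = 0.0851). All 15 antimicrobial genes were detected. Examples are the nitric oxide synthase Nos2 (7.56 ± 0.11), Acod1, the enzyme that makes itaconate (6.96 ± 0.16), the siderophore-binding protein Lcn2 (7.49 ± 0.24) and the acute-phase protein Saa3 (7.09 ± 0.31). The antimicrobial list passed (Fisher's exact test, adjusted p = 0.0135).

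Housekeeping and metabolic groups were also largely above background. All 16 oxidative phosphorylation genes were detected, with Ndufa1 of respiratory complex I at 10.12 ± 0.039. All 16 apoptosis and survival genes were detected, with the survival genes Mcl1 at 10.03 ± 0.064 and Bcl2l1 at 8.19 ± 0.085. Both lists passed (Fisher's exact test, adjusted p = 0.0135 each). Glycolysis and hypoxia genes were detected in 17 of 18 cases (adjusted p = 0.0375), with the glucose transporter Slc2a1 at 7.38 ± 0.14, Hk2 at 5.79 ± 0.17 and Egln3 not detected (3.70 ± 0.24). Without replicate 3 that list did not pass (adjusted p = 0.0959, the highest of a range from 0.00244 over the alternatives). All 14 migration and adhesion genes were detected (adjusted p = 0.0185), including the integrins Itgb2 (7.59 ± 0.031) and Itga4 (10.14 ± 0.010). Of 15 proliferation genes, 13 were detected, with Mki67 at 4.82 ± 0.12 and Cdk1 at 6.97 ± 0.10, and with Bub1 (3.57 ± 0.033) and Rrm2 (3.65 ± 0.11) not detected. Lipid and cholesterol genes were detected in 13 of 14 cases, with Hmgcs1 of sterol synthesis at 7.16 ± 0.039 and Pparg not detected (3.93 ± 0.11). Immediate early and stress genes were detected in 14 of 15 cases, with Jun at 8.36 ± 0.062 and Fosb not detected (3.80 ± 0.079). The proliferation (adjusted p = 0.151), lipid (adjusted p = 0.0851) and stress (adjusted p = 0.0730) lists did not pass Fisher's exact test. By the same test the lipid list passed without replicate 2 (adjusted p = 0.0158) and with the 99th percentile as background (0.0171). The stress list passed with detection in every array (adjusted p = 0.0484) and with the 99th percentile (0.0115). Their highest values over the alternatives were 0.217 and 0.0918.

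Across the 17 pathway lists, 9 passed the test and 250 of 264 measured entries were detected. The number of lists that passed depended on the background level. With the 90th percentile of the receptor genes as background, 0 of the 30 lists passed Fisher's exact test after adjustment, and those 9 had adjusted p between 0.0918 and 0.135. With the 99th percentile, 17 of the 30 passed, among them the inhibitory and inflammasome lists (Fisher's exact test, adjusted p = 0.0227 each).

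**Figure D2:**
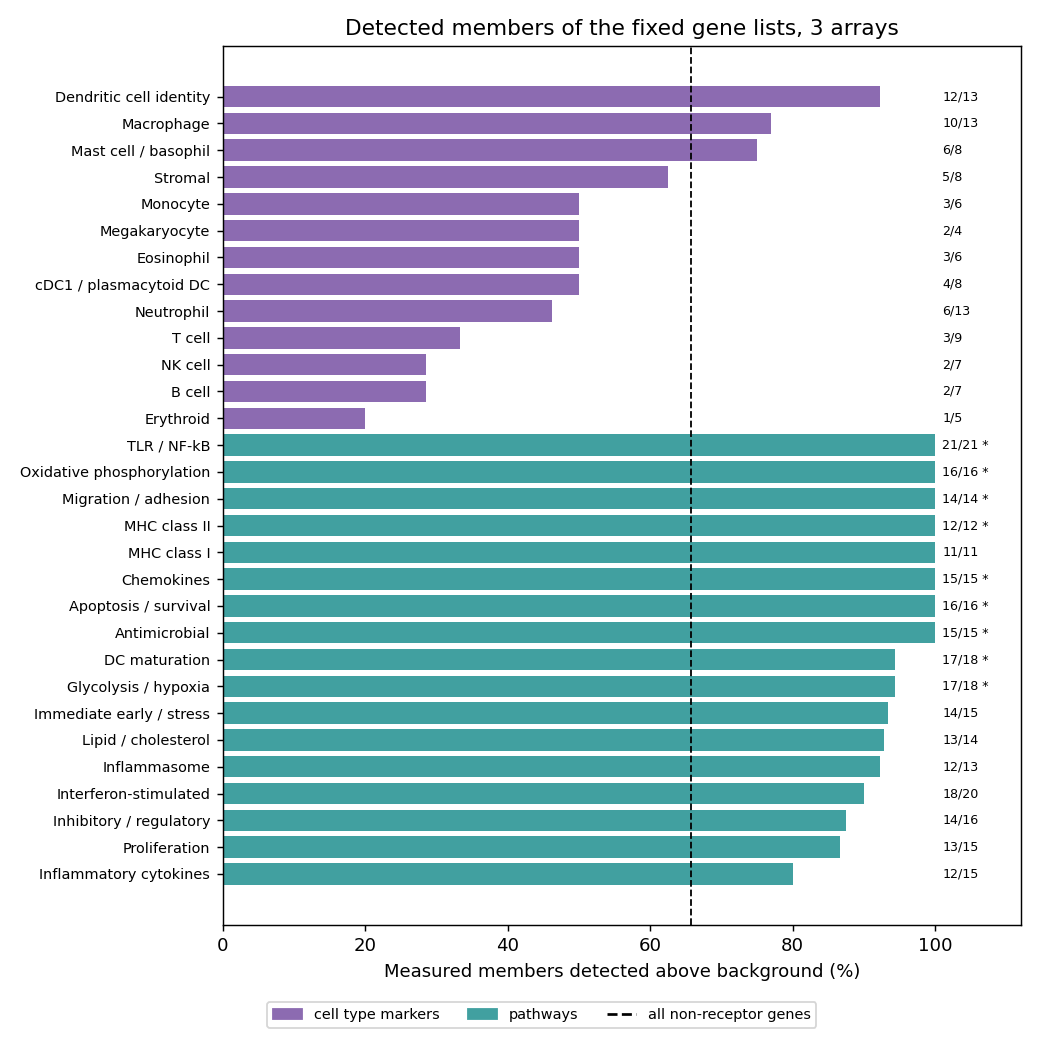
Share of the measured members of each fixed gene list that was detected above background, in percent (bars), with the counts at the right, an asterisk for a Fisher's exact test with adjusted p under 0.05, and the share of all non-receptor genes, 65.7%, as a dashed line. The 9 asterisks stand beside pathway lists. Of the cell type lists, dendritic cell identity, macrophage, and mast cell and basophil lie above the line and all others below it. None of the cell type lists passed the test, which short lists could hardly pass even with every member detected.

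Markers of cell types showed a mixed picture. Of 13 dendritic cell identity genes, 12 were detected: among them were the integrin Itgax, which encodes CD11c (6.13 ± 0.042), the cytokine receptor Flt3 (8.68 ± 0.072) and the transcription factors Zbtb46 (6.97 ± 0.072) and Irf4 (8.30 ± 0.15), while Cd209a was not detected (3.27 ± 0.074). The list did not pass the test (Fisher's exact test, adjusted p = 0.0851). Of 8 genes of cross-presenting and plasmacytoid dendritic cells, 4 were detected, and Xcr1 (3.46 ± 0.061), Clec9a (3.62 ± 0.15) and Itgae (3.89 ± 0.28) were not. Of 13 macrophage genes, 10 were detected, including Adgre1, which encodes F4/80 (6.66 ± 0.052), and Csf1r (5.38 ± 0.17), while Cd163 (3.02 ± 0.11), Mrc1 (3.40 ± 0.072) and C1qa (3.94 ± 0.094) were not. Of 6 monocyte genes, 3 were detected, with Ccr2 (3.47 ± 0.16) and F13a1 (3.52 ± 0.056) below background.

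Lineages other than dendritic cells and macrophages gave partial signal, much of it near background. Of 8 mast cell and basophil genes, 6 were detected, with carboxypeptidase Cpa3 at 6.58 ± 0.36 and the basophil protease Mcpt8 at 4.45 ± 0.39. The IgE receptor subunits Fcer1a (3.57 ± 0.22) and Ms4a2 (3.22 ± 0.11) were not. Of 13 neutrophil genes, 6 were detected, with S100a8 at 5.65 ± 0.34, S100a9 at 4.26 ± 0.20 and Mmp8 at 8.17 ± 0.20, while Ly6g (3.12 ± 0.10) and Mpo (3.47 ± 0.082) were not. Among 9 T cell genes, 3 were detected: the interleukin-7 receptor Il7r (10.19 ± 0.047), Cd3e (4.41 ± 0.12) and Bcl11b (4.26 ± 0.054). Cd3d (2.92 ± 0.16), Cd3g (3.23 ± 0.13) and Cd4 (3.46 ± 0.099) were not. The B cell list had 2 of 7 detected, Cd79b (4.45 ± 0.12) and Blk (4.17 ± 0.097). The NK cell list had 2 of 7, Gzmb (4.97 ± 0.89) and Prf1 (4.90 ± 0.21), and the erythroid list 1 of 5, Alas2 (4.62 ± 0.099). The eosinophil list had 3 of 6, the megakaryocyte list 2 of 4, and the stromal list 5 of 8 detected, including Prg2 (4.70 ± 0.57), Pf4 (6.68 ± 0.011) and Col1a1 (4.98 ± 0.027). The 99th percentile of the receptor genes was 4.83. Cd3e, Bcl11b, Cd79b, Blk, Alas2, S100a9, Mcpt8 and Prg2 lay below it. Cpa3, S100a8, Mmp8, Il7r, Gzmb, Prf1, Pf4 and Col1a1 lay above it. So did Kit (6.20 ± 0.055), Gata2 (6.11 ± 0.14) and Hdc (5.74 ± 0.027) of the mast cell list. In the stromal list Dcn (6.29 ± 0.082) and Thy1 (7.02 ± 0.18) were also above it. The other detected genes of these lists, Prss34, Col1a2 and Col3a1, lay below it. None of the 13 cell type lists passed Fisher's exact test after adjustment. Apart from the dendritic cell identity, macrophage and neutrophil lists, they held at most 9 measured genes. Lists that short could hardly pass with more detected members, since the class I list did not pass with 11 of 11 detected. With the 99th percentile as background, dendritic cell identity passed with more detected members than other genes (adjusted p = 0.0227, range 0.0227 to 0.326 over the alternatives) and the B cell list with fewer (adjusted p = 0.0276, range 0.0276 to 0.151). At an unadjusted p under 0.05, 1 list did, that of dendritic cell identity (Fisher's exact test, p = 0.0439).

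Only 2 genes passed the test for differing between the 3 infected arrays by more than genes of like signal. Gzmb, which encodes the cytotoxic protease granzyme B, measured 4.18, 5.94 and 4.79 in replicates 1, 2 and 3, a 3.38-fold span. Its values in replicates 1 and 3 were below 4.83, the 99th percentile of the receptor genes, so the size of that span is uncertain. Fxyd2, a regulator of the sodium pump, measured 6.25, 7.38 and 5.92, a 2.75-fold span. Both were highest in replicate 2, and both passed limma's test of excess variance (adjusted p = 0.0217 each) among 12351 detected genes. At an unadjusted p under 0.05 there were 565 genes, where a share of 0.05 of the genes tested is 618. The prior variance and its degrees of freedom were estimated from these same genes. A count near 618 is thus largely set by the fit and does not exclude wider excess variance. The other 13 of the 15 genes with the smallest p did not pass. They included the mast cell protease Mcpt2 (6.99 ± 0.54, adjusted p = 0.125 by limma), the receptor-modifying protein Ramp3 (10.01 ± 0.29, adjusted p = 0.117 by limma), the eosinophil granule protein Prg2 (adjusted p = 0.284 by limma) and the cytokine Il9 (7.54 ± 0.40, adjusted p = 0.317 by limma). Small RNA genes in that set were Mir350, Rny3 and Snord49b. The remaining ones were Olfr1148, Slc6a12, Rnf125, Ublcp1, Gm13213 and Slc38a2. Among members of the fixed lists, 1 passed over all genes tested (Gzmb) and 14 passed when adjusted over the list alone, in 7 lists: 5 antimicrobial genes, among them Saa3 and Lcn2, 3 neutrophil genes (S100a8, Ngp and Mmp8), Mcpt8 and Cpa3 of the mast cell list, and Ccl2, Prg2, Timp1 and Gzmb. Without replicate 2, limma's adjusted p was 0.694 for Gzmb and 0.978 for Fxyd2, and without replicate 1 it was 0.293 for Gzmb. Neither gene passed without a trend of the prior variance on signal (adjusted p = 0.951 each by limma) or with a robust prior (adjusted p = 0.983 each, the highest of ranges from 0.000296 for Gzmb and 0.00727 for Fxyd2).

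The gene lists were then compared between arrays by the median departure of their detected members from each gene's mean over the 3 arrays. Of 66 pairs of list and array, 4 departed more than all but a share of 0.002 of 10000 random lists matched on signal, where 0.132 pairs would be expected for unrelated genes. Chemokine genes were higher in replicate 2 by a median of 0.0768 log2 units, with 13 of 15 members above their mean and the largest departures in Ccl2 (0.33), Ccl6 (0.20), Cxcl3 (0.19) and Ccl9 (0.18). MHC class II genes were lower in replicate 2, with a median departure of -0.0680 and 2 of 12 members above their mean. The lowest were Marchf1 (-0.23), which encodes a ligase that removes class II molecules from the surface, the class II modulators H2-Ob (-0.23) and H2-Oa (-0.11), and H2-DMa (-0.11). The class II chains H2-Aa (-0.016), H2-Ab1 (-0.0031) and H2-Eb1 (0.017) differed little from their means. The class II departure of replicate 2 was -0.0473 without replicate 1, with 5 of 12 members above their mean, and -0.0416 without replicate 3, with 0 of 12 above. These values describe the 3 arrays and carry no test across replicates. Without matching on signal, neither departure passed (shares of 0.0106 for chemokines and 0.0118 for MHC class II), and without the detection filter the chemokine share was 0.0022.

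Neutrophil genes were higher in replicate 2 by a median of 0.176 over 6 detected members, with 4 above their mean, led by S100a8 (0.39), Ngp (0.25), Mmp8 (0.21) and Camp (0.14), while S100a9 was at -0.056. Ngp (4.27 ± 0.28) and Camp (4.85 ± 0.12) lay less than 1 log2 unit above background. Macrophage genes were higher in replicate 3 by a median of 0.131 over 10 members, with 7 above their mean, led by the complement gene C1qc (0.26), the efferocytosis receptor Mertk (0.21), Fcgr1 (0.17) and C1qb (0.15). Csf1r (-0.10) and Adgre1 (-0.022) were below their means there, and C1qc, Mertk and C1qb lay less than 1 log2 unit above background. Over all 13 measured neutrophil genes the median departure in replicate 2 was -0.042. Over the detected ones it was 0.100 without replicate 1 (rank share 0.0104) and 0.111 without replicate 3 (0.0174), and the share was 0.0030 with the mean in place of the median. The macrophage departure was 0.0621 without replicate 1 (rank share 0.051) and 0.0984 without replicate 2 (0.0052), and the share was 0.0106 with the mean and 0.549 without the detection filter.

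**Figure D3:**
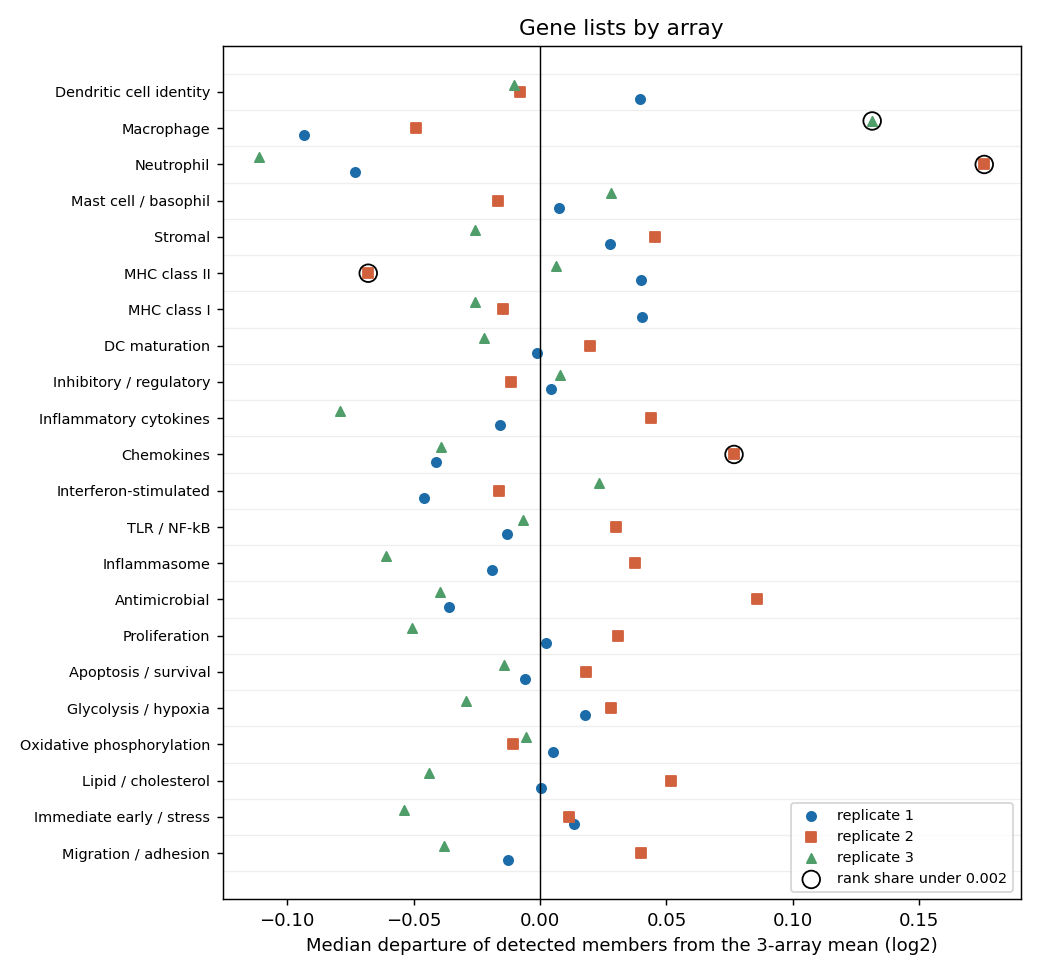
Median departure of the detected members of each gene list from the 3-array mean, in log2 units (horizontal axis), for each array (symbols), with a circle where the rank share among random lists was under 0.002. Of the 3 arrays, replicate 2 is the highest within the chemokine list, at 0.0768, and the lowest within the MHC class II list, at -0.0680.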

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

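One alternative, robust eBayes with shared prior degrees of freedom, was chosen after seeing the data, and the others before. The number of detected genes stayed within 1.5 times of 12351 in all 10 alternatives run for it. The number of lists past Fisher's exact test, 9 as reported, was 17 with the 99th percentile of the receptor background and 0 with the 90th, and 9 to 11 in the 8 other settings. At the 90th percentile the background level fell to 3.60 and 24 of the 369 list genes gained detection, and at the 99th it was 4.83 and 42 lost it. The mean SD between pairs of arrays, 0.161, was 0.167 for detected genes only, and 0.158 to 0.166 when 1 replicate was left out. The 2 genes past the variance test became 0 without a trend on mean signal and 0 with robust eBayes, which lowers the prior degrees of freedom of outlying genes by construction. With 1 shared value the robust fit again gave 2. Leaving out 1 replicate gave 1 to 4 genes, and the 4 without replicate 2 were Ramp3, Mcpt2, Mir350 and Prg2. The 4 list departures became 2 without matching on signal and 2 with the mean in place of the median, and 0 to 6 when 1 replicate was left out, where the departures of the 2 remaining arrays mirror each other. The count was 0 without replicate 2. It was 6 with the mean of all probe sets, 5 with quantile normalization and 3 without the detection filter. The antimicrobial list in replicate 2, which had a rank share of 0.0024 as reported, stood apart in those 3 settings and without replicate 3 (shares of 0.0004 to 0.0016), and the cytokine list in replicate 3, with 0.0026 as reported, stood apart with the mean of all probe sets (0.0020) and without the detection filter (0.0018). Without the detection filter the neutrophil departure in replicate 2 reversed to -0.042. The cause of these changes was not tested, except that the last one adds 7 genes at background level. Of the recomputed signals of named genes, 1179 moved by less than 1 SD and 4 by more, 3 of them with the mean of all probe sets. Much of this was fixed in advance. Leaving out 1 of 3 arrays cannot move a mean by 1 SD of those arrays, and the mean of all probe sets changes nothing for a gene with 1 probe set. The count of 1179 therefore says little on robustness. No paired analysis was possible because the samples form 1 group. An alternative pseudocount was not run, since the values are on a log scale. Signal over background limits all statements on genes near 3.95.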

Other observations

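The Fisher's exact tests of genes that differed between arrays, the neutrophil check, the use of the planned quantile normalization as a test of an explanation, and the comparison of mast cell genes between replicates 2 and 3 were chosen after the values were seen, while the test without replicate 2 was chosen before its result was seen. The genes in this paragraph and the next were also chosen after their values were seen. Type 2 cytokine and mast cell genes were detected in part: of 13 examined, 9 were above background, and 2 of these, Cpa3 and Mcpt8, also belong to the fixed mast cell and basophil list. The type 2 cytokine Il13 measured 9.04 ± 0.096 and Il9 7.54 ± 0.40, while Il4 lay near background (4.04 ± 0.066) and Il5 (3.31 ± 0.12) and Il3 (2.88 ± 0.11) were not detected. The mucosal mast cell proteases Mcpt1 (6.22 ± 0.25) and Mcpt2 (6.99 ± 0.54) were detected, and Mcpt4 (3.36 ± 0.16) and Tpsab1 (3.22 ± 0.024) were not. Genes of eicosanoid synthesis were detected in 9 of 11 cases, among them the cyclooxygenase Ptgs2 (9.48 ± 0.055), the lipoxygenase Alox5 (9.21 ± 0.061) and the leukotriene C4 synthase Ltc4s (8.18 ± 0.11), with Alox12 (3.06 ± 0.15) and Alox15 (3.54 ± 0.22) not detected.

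Of 7 C-type lectin genes, 6 were detected, with Clec4d at 7.09 ± 0.11 and Clec4e, a receptor for mycobacterial glycolipid, at 6.68 ± 0.13. A further set of 8 genes was detected in full. It held the interleukin-2 receptor chain Il2ra (10.73 ± 0.10), the costimulatory receptor Tnfrsf9 (11.22 ± 0.038), the activin subunit Inhba (8.85 ± 0.064), the retinoic acid-producing enzyme Aldh1a2 (7.54 ± 0.21) and the Notch ligands Dll4 (7.52 ± 0.13) and Jag1 (6.29 ± 0.088). Xist, the transcript of the inactive X chromosome, measured 9.35 ± 0.10, and the Y-linked Eif2s3y (2.65 ± 0.049), Kdm5d (3.20 ± 0.093) and Uty (2.64 ± 0.068) were not detected in the mean of the 3 arrays.

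Some lists held more genes that differed between the arrays than other detected genes did, counted at an unadjusted p under 0.05 in the variance test. By Fisher's exact test over the 30 lists, the chemokine (5 of 15, adjusted p = 0.00605), antimicrobial (5 of 15, adjusted p = 0.00605), cytokine (4 of 12, adjusted p = 0.0129) and neutrophil (3 of 6, adjusted p = 0.0129) lists passed, while the Toll-like receptor and NF-κB (3 of 21, adjusted p = 0.258), interferon-stimulated (3 of 18, adjusted p = 0.20) and inflammasome (1 of 12, adjusted p = 0.860) lists did not. Genes of a list are co-regulated, which makes these p-values too small, and the first 3 lists were put together after their values were seen, so whether such genes vary more in general stays open. Of their 42 detected genes 14 were counted, 11 of them highest in replicate 2, among them Ccl2, Il1b, Il6, Saa3 and Lcn2. Without replicate 2 the count was 4 of 42 (9.52%, against 5.22% of other genes; Fisher's exact test, p = 0.280), and it was 14 without replicate 1 and 11 without replicate 3, so the excess may rest on that array, and no biological explanation was tested.

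Normalization between arrays and neutrophils in that sample both stay open for the chemokine and MHC class II departures of replicate 2. Under quantile normalization the larger rank share of both was 0.00140, but that correction moved no signal of the 169 named genes by 1 SD, so it tests little. The median departure over all 13 measured neutrophil genes was -0.042, but only 2 of them, S100a8 (5.65 ± 0.34) and Mmp8 (8.17 ± 0.20), lay 1 log2 unit or more above background. No biological explanation was tested.

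Of the 6 detected genes of the mast cell and basophil list, Cpa3 and Mcpt8 had an unadjusted p under 0.05 in the variance test, a count that did not pass Fisher's exact test over the 30 lists (p = 0.0277, adjusted p = 0.139). Both genes passed limma's variance test when adjusted over the list alone (adjusted p = 0.00876 each), which does not correct for the 30 lists. Of 10 detected mast cell genes compared between replicates 2 and 3, Cpa3 fell by 0.71, beyond 3 times the SD expected of a difference (0.46), and Mcpt2 was 0.77 higher (0.43), while the other 8 lay within that bound. Over all genes none of Cpa3, Mcpt8 and Mcpt2 passed (adjusted p = 0.805, 0.842 and 0.125 by limma). Without replicate 2, Mcpt2 passed (adjusted p = 0.00217 by limma, with a range of 0.00217 to 0.984 over the alternatives). A different share of one mast cell-like population could not be excluded or shown from these genes, and no other biological explanation was tested.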
